A study of Xenopus laevis with 27 samples.

How the data were processed

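RNA abundance was measured by bulk RNA sequencing in amputated tails of the frog Xenopus laevis at 9 times after amputation. The times were 0, 30, 60 and 90 minutes (minutes post amputation, mpa), 3 and 6 hours (hpa) and 1, 3 and 7 days (dpa), with 3 libraries, A to C, at each time. Per the labels' protocols, each library held total RNA of 20 embryos, was made from 100 ng with a Lexogen SENSE kit and was sequenced as paired reads of 76 bases on an Illumina NextSeq 500. The labels call the 3 libraries of a time biological triplicates without saying whether these came from separate clutches, so p-values measure the spread between these libraries. The 60 mpa libraries have labels of their own, while the design text lists the other 8 times.

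The authors deposited a table of whole-number counts per gene for all 27 libraries and a table of normalized values for 25 of them. The submitters' processing notes name STAR 2.7.9a, HTSeq 0.6.1p1, DESeq2 1.32.0 and R 4.1.0, with no role for each. The genome build, the annotation and the strand setting of the counting are not given in the sources used here, so overlapping and antisense genes cannot be told apart. The deposited normalized signal equalled the count divided by 1 size factor per library, within 1e-06, and the factors equalled DESeq2's. Libraries 90 mpa C and 7 dpa C are not in that table, which was used for this check alone. The counts as deposited were the basis of all other values.

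The count table held 29776 genes and no rows without a gene name. Symbols were taken as deposited, and 29771 of them matched NCBI's RefSeq gene table of assembly v10.1, which was used for names alone. Xenopus laevis carries an ancient duplication of its genome, and the suffixes .L and .S mark the copies of a gene on the long and short subgenomes. These copies are similar in sequence, so reads may have been split between them in counting, and the same holds for tandem families such as mmp9, ocm4 and krt12.

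Differential expression was tested with edgeR 4.0.16 in R 4.3.3 by the quasi-likelihood test with robust estimation, TMM scaling and 1 fit over all 27 libraries with the 9 times as groups. Genes were filtered by edgeR's filterByExpr by group, which kept 22268 and dropped 7508, and the tested genes held at least 99.49% of the counts of every library. Each of the 8 later times was compared with 0 mpa, each time with the one before it (7 steps), and all 9 times jointly. P-values were adjusted by the Benjamini-Hochberg method within each comparison, and genes with an adjusted p under 0.05 are called changed. Log2 fold changes are the fitted values with a prior count of 0.125, and are given with the standard error (SE). Levels are CPM, counts scaled to a library total of 1000000 with TMM factors, as mean ± SD over 3 libraries. Against a group with no read, the fold is a lower bound, computed against a floor of 3 counts over the whole group and written as at least that fold. With 1 to 3 reads in a group the ratio of summed reads, scaled by library total and TMM factor, is given with its 95% exact counting interval. Intervals and floors cover counting error only, since no molecular identifiers are recorded in the sources used here.

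Before the data were examined, the comparisons, the alternatives, 22 gene lists and the rule for named genes were fixed. By that rule, named genes had an adjusted p under 0.05, a mean of at least 5 CPM in the higher group and a symbol that is not a serial identifier. They were the 5 highest and 5 lowest fold changes at each time among genes whose groups did not overlap, and up to 3 members of each list with the largest change in each of 3 windows (30 to 90 mpa, 3 to 6 hpa, 1 to 7 dpa). Where no member of a list passed, the member with the smallest p was eligible. Genes named for the steps between neighbouring times were chosen after their values were seen.

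The lists covered pathways (immediate early genes, inflammatory signalling, matrix proteases and inhibitors, structural matrix, developmental ligands and targets, cell cycle, heat shock and unfolded protein, p53 and apoptosis, glycolysis and hypoxia, circadian clock, posterior patterning, oxidative phosphorylation), tissues (leukocyte, erythroid, skeletal muscle, neural, notochord and cartilage, epidermis, endothelial, trunk and head organs) and RNA quality (ribosomal proteins, mitochondrially encoded). The mitochondrially encoded list matched 0 genes of the table and was not tested. The other 21 lists were tested at 8 times, 168 tests adjusted together, with camera in limma 3.58.1 at the preset correlation of 0.01 between genes and again with a correlation estimated from the data. The preset correlation passed 91 of 168 tests and the estimated one 37. Because random regroupings of the libraries also passed many tests with the preset value, the text says that a list rose or fell only where the estimated correlation also passed. For each list the number of changed members is given over all genes tested and adjusted over the list alone.

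Total counts lay between 4186706 and 6332675 in 24 libraries, and were 1207557 in 6 hpa C, 367958 in 90 mpa C and 19187 in 7 dpa C. In 7 dpa C 3 reads correspond to 51.7 CPM, so that library says little of any single gene. CPM levels at 7 dpa are therefore given for A and B separately. Log2 fold changes, SEs, adjusted p and counts of changed genes at 7 dpa include 7 dpa C unless its omission is stated. The common biological coefficient of variation was 50.6%. The procedure was tested on simulated counts drawn from the real means and depths of the 22268 genes, of which 21612 passed the filter. Changed genes were drawn only from those with a mean of at least 5 CPM, so the shares recovered do not cover lower genes. Each gene had the same fitted spread in all libraries. Libraries that stand apart, such as 1 dpa B, were thus not imitated, and false calls in the real data may be more frequent. At 3 dpa it recovered 5.88% of 68 genes changed 2-fold, 65.2% of 66 changed 4-fold and 97% of 66 changed 16-fold, with 3 false calls among 114. At 7 dpa these shares were 5.88%, 56.1% and 95.5%. False calls were 6 of 115 at 90 mpa and 13 of 120 at 1 dpa, above the share of 0.05 aimed at, and 2 to 5 at the other 6 times. Changes of 2-fold were thus mostly not detectable.

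Alternatives were RLE scaling, no filter on low counts, a fit of the 6 libraries of a comparison alone, DESeq2 1.42.0, a block for the library letter, summed .L and .S copies for the lists, the estimated correlation, and leaving out each library. After the data were seen, fits without 90 mpa C and 7 dpa C and without 5 shallow or low-complexity libraries were added. No pair of libraries of a time agreed within sampling noise, the lowest chi-square per degree of freedom being 5.98. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9. Unamputated tails of the later times were not analysed here.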

Results

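Gene expression was followed in regenerating tails of Xenopus laevis, whose tadpoles regrow an amputated tail, from 0 mpa to 7 dpa. The stated purpose was to describe how expression changed with time over regeneration. Each of the 9 times had 3 libraries (n = 3), and the tails at 0 mpa were the baseline. Total counts were between 4186706 and 6332675 in 24 libraries, against 1207557 in 6 hpa C, 367958 in 90 mpa C and 19187 in 7 dpa C. Thinned to 1000000 counts, 1 dpa B gave 16235 genes and 3 dpa B 18672, while 6 hpa C gave 18885, 90 mpa B 19118 and the other libraries of that depth 19750 to 22233. Pearson's r of log2 CPM across genes, which are not independent replicates, was 0.837 to 0.951 between libraries of 1 time, except for pairs with 90 mpa C (0.684 and 0.711) and with 7 dpa C (0.444 and 0.449).

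**Figure D1:**
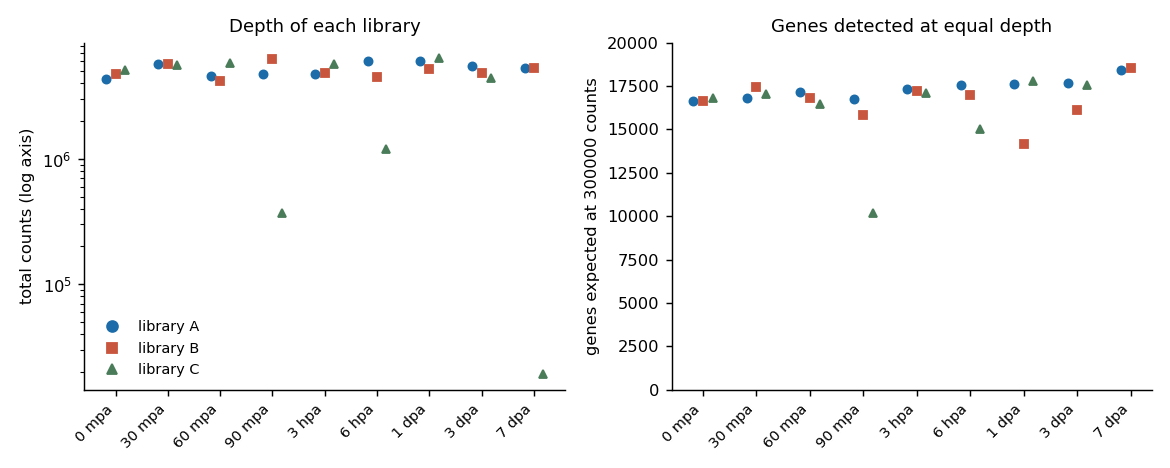
Total counts (left, log axis) and genes expected after thinning to 300000 counts (right, linear axis) for each of the 27 libraries, by time after amputation; each point is 1 library, and 7 dpa C, with 19187 counts, has no value on the right. Libraries 6 hpa C, 90 mpa C and 7 dpa C lie below the other 24 in depth, and 90 mpa C gave 10164 genes at equal depth.

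Over the 9 times, 3524 of 22268 genes (15.8%) changed in the joint test. The highest fitted mean of these genes lay at 0 mpa for 580, at 30 mpa for 185, at 60 mpa for 273, at 90 mpa for 475, at 3 hpa for 447, at 6 hpa for 424, at 1 dpa for 313, at 3 dpa for 407 and at 7 dpa for 420. These counts moved with the libraries, and so did the total of 3524 that they share out. Without the A libraries they were 261, 71, 95, 267, 165, 128, 96, 155 and 216 in order of time. Without the B libraries they were 325 at 0 mpa and 132 at 1 dpa, and without the C libraries 227 at 90 mpa and 233 at 6 hpa. Against 0 mpa the number of changed genes was 84 at 30 mpa, 257 at 60 mpa, 752 at 90 mpa, 764 at 3 hpa, 814 at 6 hpa, 1016 at 1 dpa, 2054 at 3 dpa and 1767 at 7 dpa. Higher genes made up all 84 at 30 mpa, and lower genes were the majority at 3 dpa (1110 of 2054) and 7 dpa (1182 of 1767). Without the A libraries the joint count was 1454, and without the 5 libraries 90 mpa C, 6 hpa C, 1 dpa B, 3 dpa B and 7 dpa C, a choice made after the data were seen, it was 6311.

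**Figure D2:**
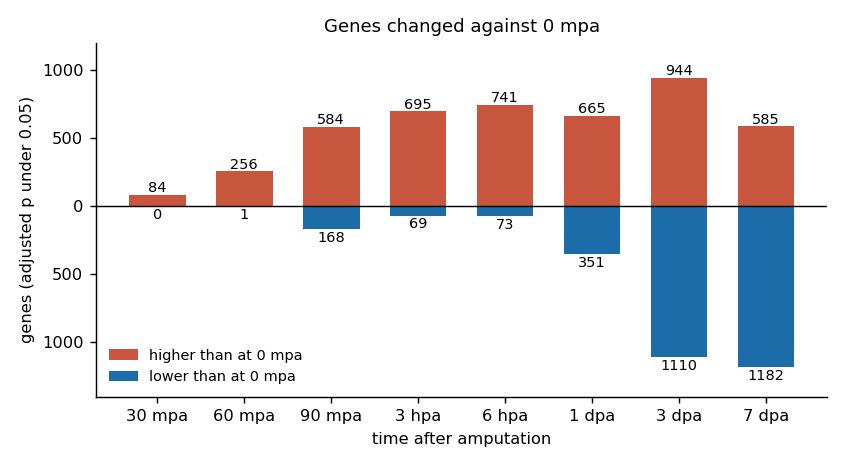
Number of genes changed against 0 mpa (adjusted p under 0.05, edgeR) at each later time, with higher genes drawn above 0 and lower genes below. Higher genes numbered 84 at 30 mpa and 944 at 3 dpa, and lower genes 0 at 30 mpa and 1182 at 7 dpa.

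At 30 mpa, genes of the immediate early response rose. Fos.L, a subunit of the AP-1 transcription factor, went from 1.07 ± 0.98 to 833 ± 112 CPM, a log2 fold change of 9.54 ± 0.62 (SE, adjusted p = 9.27e-18). Egr4.L, a zinc finger transcription factor, had no read at 0 mpa and was at least 76.1-fold higher. Fosb.L rose by 7.04 ± 0.97, egr2.L by 6.24 ± 0.80, ch25h.S, which makes an oxidised cholesterol, by 6.61 ± 0.68, and hes1.S, a repressor acting downstream of Notch, by 2.59 ± 0.44. Of 74 immediate early genes 43 rose over all genes tested and 56 adjusted over the list alone (list adjusted p = 8.11e-09 with an estimated correlation), and their median log2 fold change was 2.63 (2.65 with members at 0 reads set to their bound).

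Among 96 developmental ligands and targets 3 rose at 30 mpa, 7 adjusted over the list alone, and the list rose (adjusted p = 0.0298 with an estimated correlation). The erythroid list rose as a set (adjusted p = 0.00942), although 0 of its 31 members passed over all genes and 9 did adjusted over the list alone. Its baseline was uneven. Relative to the 0 mpa mean, the mean log2 level was -0.745 in 0 mpa B, 0.416 in A and 0.329 in C, and 0.841 to 1.125 at 30 mpa. Alas2.L, the first enzyme of heme synthesis in red cells, was at 399 ± 49.3 CPM against 139 ± 89.5 at 0 mpa (adjusted p = 0.0713; 0.0357 without library 0 mpa A, which held 872 of its reads against 153 in 0 mpa B). No gene fell at 30 mpa by edgeR's quasi-likelihood test, where 825 genes in either direction had an unadjusted p under 0.05, and DESeq2 called 95 higher and 1 lower. The fit of the 6 libraries alone gave 123 higher and 13 lower genes, the fit without a filter 125 and 9, and the fit without the 5 shallow or low-complexity libraries 198 and 13.

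At 60 mpa immediate early genes were again far above their level at 0 mpa. Fos.L reached 1319 ± 51 CPM (log2 fold change 10.21 ± 0.63, adjusted p = 8.28e-19) and fosb.L 470 ± 5.02 CPM (9.67 ± 1.02). Fosl1.L, another AP-1 subunit, was at 254 ± 54.7 CPM, up by 9.24 ± 0.74. Egr4.L was at least 187-fold higher, and wnt9b.2.L, a Wnt ligand, at least 35.6-fold. Of the immediate early list 53 of 74 rose, 60 adjusted over the list alone (list adjusted p = 5.09e-09 with an estimated correlation).

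Inflammatory genes also rose by 60 mpa, 4 of 40 and 7 adjusted over the list alone (adjusted p = 0.0298 with an estimated correlation). Ptgs2.L, the inducible enzyme of prostaglandin synthesis, went from 21.9 ± 3.90 to 679 ± 50.2 CPM (4.95 ± 0.46). Of 47 matrix proteases and inhibitors 7 rose, 10 adjusted over the list alone (adjusted p = 0.00942), and of 22 clock genes 3 rose by either adjustment (adjusted p = 0.0298). Btg2.S, an antiproliferative gene on both the immediate early list and the p53 and apoptosis list, rose by 4.54 ± 0.39. Single genes of lists that did not rise as a set were pfkfb3.S, an activator of glycolysis (3.81 ± 0.59), and cldn7.L, a tight junction protein of epithelia (1.87 ± 0.38). The 1 lower gene of the 257 was znf423.L (fell by 2.85 ± 0.71, adjusted p = 0.0182), whose adjusted p was 0.0523 without 0 mpa A, 0.102 without 0 mpa B, 0.248 without 60 mpa B and 0.0966 without 60 mpa C. Without 0 mpa B 171 genes passed, the 6 libraries alone gave 500, and the fit without the 5 shallow or low-complexity libraries gave 740.

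At 90 mpa, matrix proteases and inflammatory genes were above their level at 0 mpa, as at 60 mpa. Mmp8.L, a collagenase, went from 0.320 ± 0.555 to 98.2 ± 35.0 CPM (log2 fold change 8.14 ± 0.88, adjusted p = 1.27e-07), and mmp1.S, another collagenase, rose by 5.28 ± 0.55. The S copy of mmp8 was already at 21.8 CPM at 0 mpa. Reads of lep.L, the gene for leptin, were 166 times as frequent (95% counting interval 56.3 to 807), and cxcl8.S, a chemokine for neutrophils, was at least 33.6-fold higher, both from reads in 90 mpa A and B alone. Of 47 matrix proteases and inhibitors 10 rose, 12 adjusted over the list alone (adjusted p = 0.00559 with an estimated correlation). Of 40 inflammatory genes 6 rose and 0 fell, 15 and 1 adjusted over the list alone (adjusted p = 0.032). The shallow library 90 mpa C stood apart. Relative to the 0 mpa mean, the mean log2 level of proteases was 1.374, 1.172 and -0.113 in A, B and C. That of inflammatory genes was 1.414, 1.335 and -0.677.

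Of the immediate early list 56 of 74 rose and 0 fell at 90 mpa, 61 and 1 adjusted over the list alone (adjusted p = 1.77e-07 with an estimated correlation), led by fosb.L (9.64 ± 1.02) and fosl1.L (9.40 ± 0.75). Of 22 clock genes 4 rose by either adjustment (adjusted p = 0.032): both copies of bhlhe40, a repressor of clock transcription, arntl.L and per1.L. Bhlhe40.L was at 475 ± 106 CPM against 13.0 ± 2.56, and rose by 5.18 ± 0.39, arntl.L by 2.21 ± 0.38 and per1.L by 2.16 ± 0.41. Other risers were pmepa1.S, a target of TGF-beta signalling (4.67 ± 0.50), slc2a1.L, a glucose transporter (2.99 ± 0.38), mcl1.L, an inhibitor of apoptosis (2.96 ± 0.40), sall4.L, a zinc finger factor of progenitor cells (2.89 ± 0.46), and thbs1.L, an adhesive matrix glycoprotein (2.57 ± 0.38). Poc5.L, a centriole gene, was at 8.51 ± 1.65 CPM at 0 mpa and had no read at 90 mpa, at least 28.4-fold lower. The count of 752 was 386 without 0 mpa A, 388 without 0 mpa B, 1212 without 90 mpa A, 233 in the 6 libraries alone and 1887 without the 5 shallow or low-complexity libraries.

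At 3 hpa, protease, inflammatory and immediate early genes were high. Mmp8.L reached 376 ± 38.0 CPM (log2 fold change 10.11 ± 0.89, adjusted p = 1.38e-09) and fosl1.L 414 ± 60.1 CPM (9.95 ± 0.75). Noxo1.1.L, an organiser of NADPH oxidase, was at least 95-fold higher, cxcl8.S at least 91.7-fold and stc1.L, a secreted glycoprotein hormone, at least 80.2-fold. Reads of lep.L were 347 times as frequent (118 to 1680), and ptgs2.L was at 655 ± 68.0 CPM (adjusted p = 2.74e-12). Cyp26a1.S, which degrades retinoic acid, fell by 3.66 ± 0.48, from 90.0 ± 43.5 to 7.15 ± 3.10 CPM.

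The inflammatory list had 9 of 40 higher members at 3 hpa, 16 adjusted over the list alone (adjusted p = 0.00307 with an estimated correlation), the protease list 13 of 47 and 17 (adjusted p = 0.0014) and the immediate early list 54 of 74 and 61 (adjusted p = 1.76e-07). Slc2a1.L was at 494 ± 5.07 CPM (3.69 ± 0.39). Sall4.L rose by 3.12 ± 0.45, sox7.L, an endothelial transcription factor, by 2.52 ± 0.50, xbp1.L, a factor of the unfolded protein response, by 2.01 ± 0.36, and bag3.L, a co-chaperone, by 1.61 ± 0.35. Clock genes bhlhe40.L (4.69 ± 0.39), arntl.L (2.85 ± 0.38) and per1.L (2.31 ± 0.40) were also up, but the clock list had an adjusted p of 0.0699 with an estimated correlation. Besides cyp26a1.S, foxb1.L, a forkhead factor, fell by 3.28 ± 0.57, p2ry11.L, a nucleotide receptor, by 2.88 ± 0.47 and snai2.S, a factor of neural crest and epithelial-mesenchymal transition, by 2.73 ± 0.49. The 6 libraries alone gave 2415 genes in place of 764, the fit without 90 mpa C and 7 dpa C 1205, and the fit without the 5 shallow or low-complexity libraries 2071.

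At 6 hpa, epidermal, leukocyte and protease genes were up. Lamb3.S, a laminin chain of epidermal basement membranes, was at 167 ± 28.4 CPM, and its reads were 2060 times as frequent as at 0 mpa, where 1 read was seen (369 to 81300, adjusted p = 3.97e-13). Reads of mmp9.2.S, a gelatinase, were 559 times as frequent (99.8 to 22100). Mmp1.S was at 662 ± 194 CPM (log2 fold change 7.25 ± 0.59). Of 72 epidermal genes 17 rose, 18 adjusted over the list alone (adjusted p = 0.0298 with an estimated correlation), among them cldn7.L (2.44 ± 0.38) and klf5.S, a transcription factor of epithelia (2.88 ± 0.56).

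The leukocyte list rose at 6 hpa, with 7 of 43 members higher, 14 adjusted over the list alone (adjusted p = 0.0213 with an estimated correlation). Cxcr4.S, a chemokine receptor of migrating cells, went from 8.95 ± 1.17 to 37.9 ± 8.05 CPM (2.06 ± 0.43). The protease list had 14 of 47 higher members and 15 adjusted over the list alone (adjusted p = 0.00239), the inflammatory list 8 of 40 and 16 (adjusted p = 0.0122) and the immediate early list 46 of 74 and 56 (adjusted p = 1.22e-05). Mmp8.L was up by 9.35 ± 0.89, with 52.6, 126 and 504 CPM in A, B and C, and pmepa1.L by 5.98 ± 0.56. Pthlh.S, a hormone related to parathyroid hormone, was at least 48.8-fold higher, stc1.L at least 59-fold and mmp13l.L, a collagenase, at least 21.5-fold. Cyp26a1.L fell by 4.84 ± 0.83, mafa.S, a transcription factor, by 2.98 ± 0.63 and bcl11b.L, a transcription factor, by 2.88 ± 0.60.

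Cell cycle genes had 0 higher and 1 lower member of 80 at 6 hpa (0 adjusted over the list alone) and a median log2 fold change of -0.50, with an adjusted p of 3.43e-06 at the preset correlation and an adjusted p = 0.12 with an estimated correlation. The lower member was espl1.L, the protease separase (fell by 1.82 ± 0.55, adjusted p = 0.0429). Its adjusted p was 0.249 without 0 mpa A, 0.0951 without 0 mpa B, 0.163 without 6 hpa B, 0.238 without 6 hpa C and 0.0507 in the 6 libraries alone. The higher and lower counts of 741 and 73 were 625 and 151 with RLE scaling, and 719 and 256 with DESeq2. In all, 814 genes passed, against 494 without 0 mpa A, 470 without 0 mpa B, 1359 without 90 mpa C and 7 dpa C, and 1607 without the 5 shallow or low-complexity libraries.

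At 1 dpa, matrix proteases and leukocyte genes were high and muscle genes were low. Mmp9.2.S was at 153 ± 14.9 CPM, its reads 1950 times as frequent as at 0 mpa (350 to 77200, adjusted p = 2.15e-16). Mmp11.L, the protease stromelysin 3, rose by 7.32 ± 0.58 and mmp8.L by 9.68 ± 0.89, and mmp13l.L was at least 134-fold higher. The other copy, mmp8.S, rose by 4.01 ± 0.51, from 21.8 to 351 CPM. Lsp1.L, a leukocyte cytoskeletal protein, went from 31.3 ± 5.59 to 232 ± 48.1 CPM (2.89 ± 0.36). Of 71 skeletal muscle genes 30 fell and 0 rose, 44 and 1 adjusted over the list alone (adjusted p = 0.0088 with an estimated correlation), with a median log2 fold change of -1.41, which members at 0 reads set to their bound left at -1.41.

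The protease list had 14 higher and 1 lower of 47 members at 1 dpa, 19 and 2 adjusted over the list alone (adjusted p = 0.00307 with an estimated correlation), the leukocyte list 8 higher of 43 and 12 (adjusted p = 0.0244), the inflammatory list 9 of 40 and 12 (adjusted p = 0.0499) and the immediate early list 31 of 74 and 43 (adjusted p = 0.00261). Reads of lamb3.S were 2850 times as frequent as at 0 mpa (511 to 113000) and those of lep.L 156 times (53.1 to 758), while slc25a18.S, a mitochondrial glutamate carrier, was at least 55.3-fold higher. Dusp5.L, a phosphatase of ERK, rose by 4.28 ± 0.45, while dusp5.S changed by 0.82 ± 0.41. Bhlhe40.L remained up by 2.77 ± 0.36, per1.L by 1.68 ± 0.39 (adjusted p = 0.00394) and arntl.L by 1.60 ± 0.37 (adjusted p = 0.00317). The adjusted p of per1.L was 0.0776 without 0 mpa A, 0.0508 without 1 dpa B and 0.0511 in the 6 libraries alone. That of arntl.L was 0.0501 without 0 mpa B. Hes5.1.L, a Notch target of neural progenitors, was lower by a ratio of 105 (28.5 to 872), and kcnj10.L, a potassium channel of glia, at least 29.2-fold lower.

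The 1016 genes at 1 dpa were 665 higher and 351 lower, with RLE scaling 580 and 502, and with DESeq2 702 and 645. Library 1 dpa B detected the fewest genes at 1000000 counts and correlated less with A (0.847) and C (0.851) than these did with each other (0.951). The count was 604 without 0 mpa A, 501 without 0 mpa B, 1931 without 90 mpa C and 7 dpa C, and 2016 without the 5 shallow or low-complexity libraries.

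**Figure D3:**
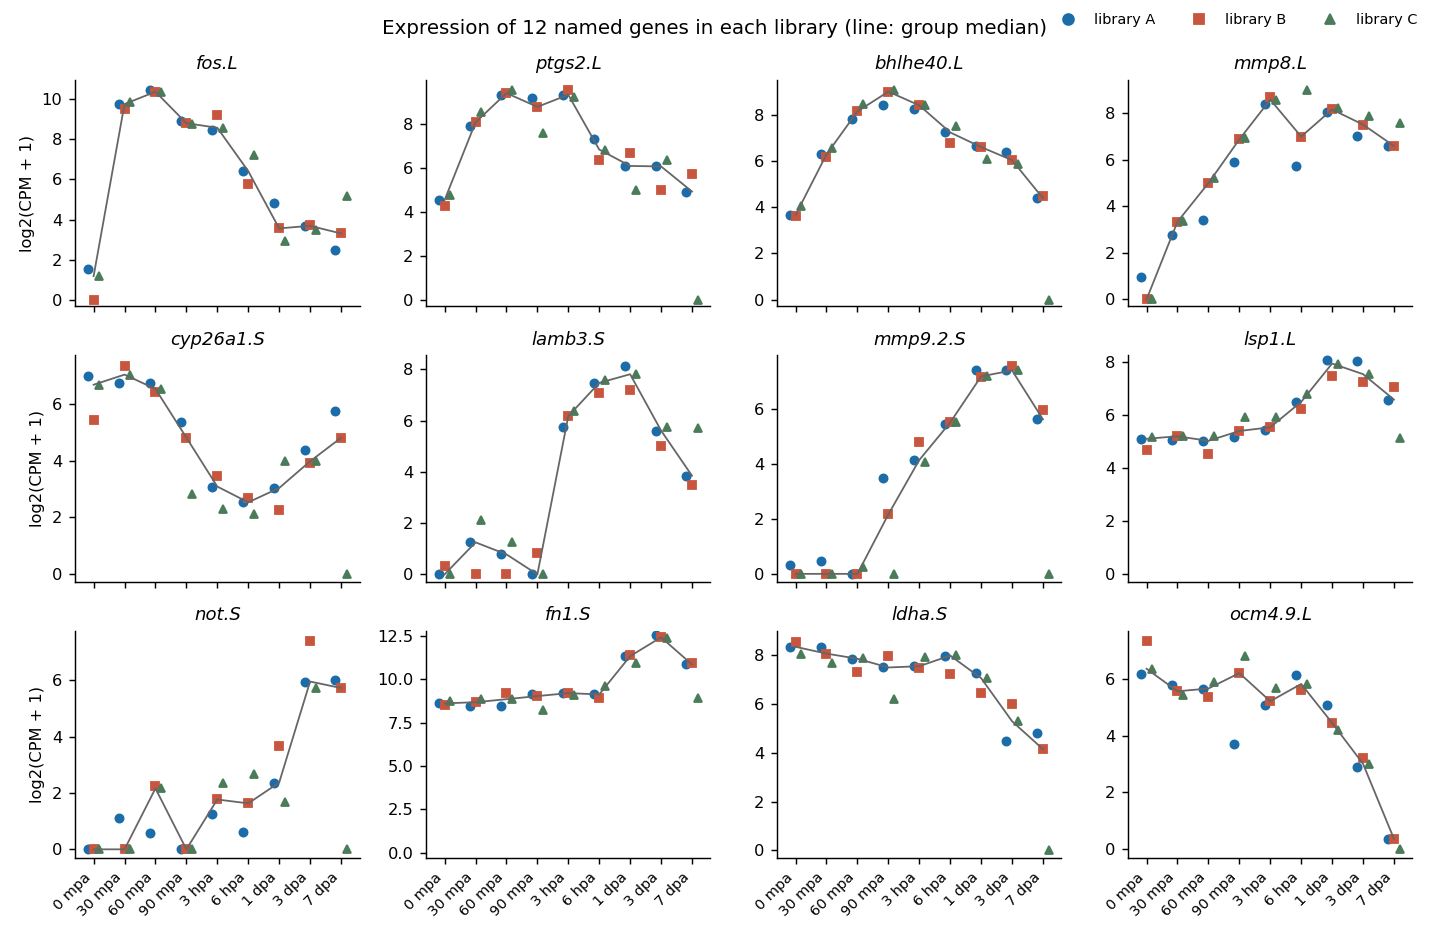
Expression of 12 named genes as log2(CPM + 1) in each library (points, shaped by library letter) by time after amputation, with a line through the group medians. Fos.L rose to 833 CPM at 30 mpa, fn1.S to 5625 CPM at 3 dpa, and ocm4.9.L fell from 104 CPM at 0 mpa; many genes read 0 in 7 dpa C, where 3 counts equal 51.7 CPM.

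At 3 dpa, matrix protease and posterior patterning genes were high, and muscle, erythroid and respiratory chain genes were low. Not.S, a homeobox gene of the notochord, was at 92.8 ± 63.3 CPM with no read at 0 mpa, at least 385-fold higher (adjusted p = 1.26e-06), and tbxt.L, the brachyury gene, rose from 0, 2 and 6 reads in A, B and C at 0 mpa to 134, 108 and 97 (20.3 ± 1.12 CPM, adjusted p = 0.00229). Fn1.S, the matrix protein fibronectin, went from 393 ± 37.1 to 5625 ± 381 CPM (log2 fold change 3.84 ± 0.40). Reads of mmp9.2.S were 2240 times as frequent (403 to 88700) and stc1.L was at least 207-fold higher. Of 45 posterior patterning genes 14 rose and 2 fell, 15 and 3 adjusted over the list alone (adjusted p = 0.037 with an estimated correlation).

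Of 71 skeletal muscle genes 48 fell and 1 rose at 3 dpa, 53 and 1 adjusted over the list alone (adjusted p = 0.000816 with an estimated correlation), with a median of -2.50 by either treatment of members at 0 reads. Prkag3.L, an AMP kinase subunit of muscle, had no read at 3 dpa and was at least 66.1-fold lower, and bves.L, a membrane protein of muscle, at least 39.6-fold. Of 66 oxidative phosphorylation genes 25 fell, 57 adjusted over the list alone (adjusted p = 0.0298), such as ndufs8.L of complex I (fell by 2.26 ± 0.46). Of 31 erythroid genes 16 fell, 24 adjusted over the list alone (adjusted p = 0.0088). Of 60 glycolysis and hypoxia genes 17 fell and 1 rose, 22 and 1 adjusted over the list alone (adjusted p = 0.0636 with an estimated correlation).

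Leukocyte genes had 7 higher of 43 at 3 dpa, 13 adjusted over the list alone (adjusted p = 0.037 with an estimated correlation), among them was.L, an actin regulator of blood cells (3.06 ± 0.78), and csf3r.L, the receptor of granulocyte colony-stimulating factor (2.94 ± 0.62). The protease list had 19 higher and 1 lower of 47, 22 and 1 adjusted over the list alone (adjusted p = 0.000973), and the immediate early list 37 of 74 higher, 40 higher and 1 lower adjusted over the list alone (adjusted p = 0.00293). The inflammatory list, with 9 of 40 and 10, had an adjusted p = 0.164 with an estimated correlation, and hmox1.S, a heme-degrading enzyme, rose by 3.98 ± 0.81. Inhba.L, an activin subunit, rose by 4.77 ± 1.00, one of 19 higher developmental ligands and targets of 96, 23 adjusted over the list alone (adjusted p = 0.0511 with an estimated correlation).

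Neural genes split at 3 dpa into 5 higher and 7 lower of 66, the same adjusted over the list alone (adjusted p = 0.57 with an estimated correlation). Dcx.L, a microtubule protein of young neurons, rose from 0.336 ± 0.582 CPM to 9.49, 35.9 and 10.2 CPM in A, B and C (adjusted p = 0.000142), and olig2.L, a factor of the oligodendrocyte lineage, was at least 30.4-fold lower. Notochord and cartilage genes split into 10 higher and 6 lower of 43, 11 and 7 adjusted over the list alone (adjusted p = 0.935), a list whose median of -0.26 and mean of 0.24 differ in sign. Within it cnmd.S, the cartilage protein chondromodulin, fell by 4.92 ± 0.99. Cat2.L was at 17.3 ± 5.65 CPM at 0 mpa and had no read, at least 97-fold lower, and tf.L, the iron carrier transferrin, rose by 3.83 ± 1.00. Of 80 cell cycle genes 1 rose, 0 adjusted over the list alone (adjusted p = 0.969 with an estimated correlation, median 0.05, mean -0.06). It was ccne1.S, a cyclin of S phase entry (2.72 ± 0.86, adjusted p = 0.0327). Ccne1.S lost its call without 0 mpa A (0.146), 0 mpa B (0.114), 0 mpa C (0.0598), 3 dpa A (0.0533) or 3 dpa B (0.221). Its call was also lost with no filter (0.0501), in the 6 libraries alone (0.0606) and without the 5 shallow or low-complexity libraries (0.0773). The count of 2054 was 1341 without 0 mpa A, 1285 without 0 mpa B and 3587 without the 5 shallow or low-complexity libraries.

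At 7 dpa, muscle, respiratory and glycolytic genes were low in libraries A and B. The fold changes, adjusted p and counts of changed genes below also include the shallow library 7 dpa C. Ocm4.9.L, an oncomodulin gene of the calcium-binding parvalbumin family, went from 104 ± 47.7 CPM at 0 mpa to 0.286 in A and 0.290 in B (log2 fold change -8.37 ± 0.75, adjusted p = 5.49e-13), and ocm4.2.S fell by 8.32 ± 0.88. Ryr3.L, a calcium release channel, fell by 6.62 ± 1.13, and myoz1.L, a protein of the muscle Z line, had no read, at least 32.5-fold lower. Of 71 skeletal muscle genes 51 fell and 0 rose, 55 and 1 adjusted over the list alone (adjusted p = 5.78e-05 with an estimated correlation), with a median of -3.46 by either treatment of members at 0 reads.

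Of 66 oxidative phosphorylation genes 47 fell at 7 dpa, 58 adjusted over the list alone (adjusted p = 0.00307 with an estimated correlation), with cyc1.S, cytochrome c1, down from 879 ± 81.4 CPM to 185 in A and 171 in B (fell by 2.50 ± 0.41). Of 60 glycolysis and hypoxia genes 16 fell, 20 adjusted over the list alone (adjusted p = 0.0047), among them pfkm.L, the phosphofructokinase of muscle (fell by 5.06 ± 1.04), ldha.S, a lactate dehydrogenase (fell by 3.94 ± 0.46), and pfkp.L, another phosphofructokinase (fell by 3.92 ± 0.46). The S copy of pfkp had a log2 fold change of -0.275 ± 0.454. Whether the respiratory falls at 3 and 7 dpa and the glycolytic fall at 7 dpa were separate from that of muscle genes was not tested. Of 31 erythroid genes 18 fell and 1 rose, 23 and 1 adjusted over the list alone (adjusted p = 0.0057). That list includes tmod4.L, a tropomodulin that is also expressed in muscle, which fell by 4.48 ± 0.45.

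Proteases were also up at 7 dpa, 17 of 47 and 22 adjusted over the list alone (adjusted p = 0.00307 with an estimated correlation). Mmp8.L was at 94.1 and 95.1 CPM in A and B (8.31 ± 0.89), and mmp8.S rose by 2.63 ± 0.49. Of 74 immediate early genes 23 were up, 28 adjusted over the list alone (adjusted p = 0.0351). Whether these are the members called at 3 dpa was not counted. Shh.S, the hedgehog ligand, was at 30.8 and 37.1 CPM in A and B against 4.53 ± 2.05 (2.74 ± 0.60). Larval skin genes itln1.L, an intelectin (fell by 4.58 ± 0.45), and krt12.4.S, a keratin (fell by 5.57 ± 0.79), were among 6 lower and 5 higher epidermal genes of 72, 11 and 6 adjusted over the list alone (adjusted p = 0.462 with an estimated correlation). Igf3.L, an insulin-like growth factor, had no read, at least 54-fold lower. Mcm7.L, a helicase subunit of DNA replication, was at 28.1 ± 5.19 CPM at 0 mpa and at 74.1 and 64.7 CPM in 7 dpa A and B. In 7 dpa C 7 reads gave 121 CPM. The gene rose by 1.45 ± 0.43 (adjusted p = 0.0199). Its adjusted p was 0.099 without 0 mpa B, 0.0796 without 0 mpa C and 0.0913 without 7 dpa A. Mcm7.L was the 1 higher cell cycle gene of 80, 0 adjusted over the list alone (list adjusted p = 0.607 with an estimated correlation).

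Some of the highest fold changes at 7 dpa rested on the 19187 counts of 7 dpa C. Skap2.S had 4, 7 and 15 reads in A, B and C, clec11a.L 8, 62 and 11, and nemp1.S 17, 29 and 15. Without 7 dpa C their log2 fold changes were 2.14 (adjusted p = 0.694), 4.78 (adjusted p = 0.119) and 3.75 (adjusted p = 0.154), against 8.68, 8.24 and 8.13 with it, and without 0 mpa A the adjusted p of skap2.S was 0.0667. The count of 1767 was 1106 without 7 dpa A, 1088 without 7 dpa B, 1789 without 7 dpa C and 3556 without the 5 shallow or low-complexity libraries.

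**Figure D4:**
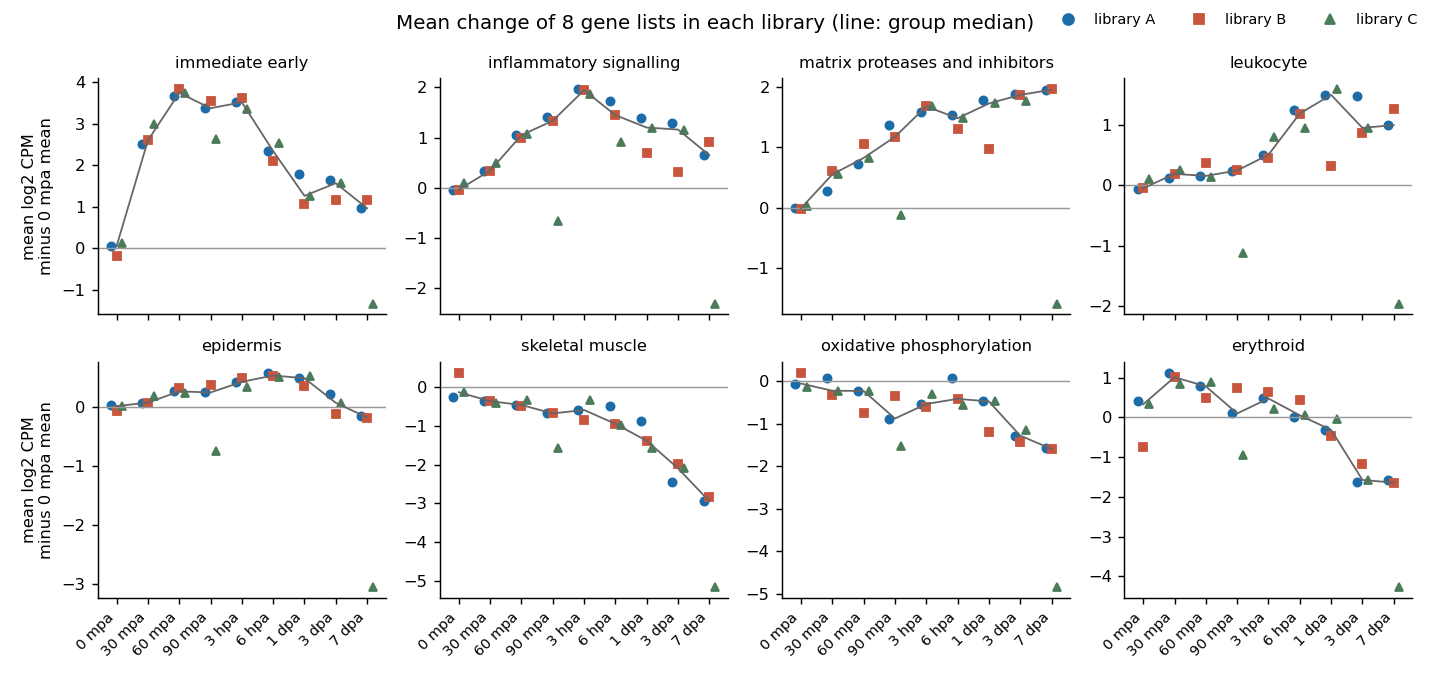
Mean log2 CPM of the members of 8 gene lists in each library, minus the mean of the 0 mpa libraries, by time after amputation; points are libraries, shaped by letter, and the line joins group medians. Immediate early genes rose at 30 mpa (43 of 74 changed) and skeletal muscle genes fell at 7 dpa (51 of 71); 7 dpa C lies lowest in every panel, with 19187 counts.

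Between neighbouring times fewer genes passed than against 0 mpa. From 30 to 60 mpa 42 genes rose and 0 fell (678 in either direction had an unadjusted p under 0.05, and DESeq2 called 62 and 0), with lep.L up by 5.78 ± 0.94 and fosl1.L by 4.39 ± 0.52. From 60 to 90 mpa 13 rose and 1 fell, and the risers included mmp1.S (2.44 ± 0.47, adjusted p = 0.0147) and pmepa1.S (2.17 ± 0.43, adjusted p = 0.0167). The adjusted p of mmp1.S was 0.224 without 60 mpa A, 0.168 without 60 mpa B, 0.103 without 60 mpa C, 0.0575 without 90 mpa B and 0.0528 in the 6 libraries alone. That of pmepa1.S was 0.262 without 60 mpa A, 0.113 without 60 mpa C, 0.15 without 90 mpa C, 0.197 without 90 mpa C and 7 dpa C and 0.186 in the 6 libraries alone. From 90 mpa to 3 hpa 6 rose and 1 fell, and lamb3.S rose by 7.36 ± 0.77. These and the following step genes were chosen after their values were seen.

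From 3 to 6 hpa 15 genes rose and 35 fell, and the fall included ptgs2.L (fell by 2.49 ± 0.41) and fos.L (fell by 2.23 ± 0.42, adjusted p = 0.00242; 0.108 without 6 hpa B). From 6 hpa to 1 dpa 25 rose and 49 fell, with mmp11.L up by 2.65 ± 0.44. In that step fos.L fell by 2.62 ± 0.43 (adjusted p = 0.000301; 0.183 in the 6 libraries alone, 0.0812 without the 5 shallow or low-complexity libraries). From 1 to 3 dpa 29 rose and 132 fell (42 and 104 with RLE scaling), with stc1.L up by 4.46 ± 0.79, while cat2.L fell by 7.84 ± 1.04 on the fitted scale, with no read at 3 dpa. In the 6 libraries alone neither of these calls was made (adjusted p of 0.1 for stc1.L and 0.211 for cat2.L). From 3 to 7 dpa 28 rose and 161 fell, with cnmd.S up by 5.12 ± 1.02, while ocm4.9.L fell by 4.54 ± 0.75.

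The step counts moved with single libraries. The 42 genes from 30 to 60 mpa were 17 without 30 mpa A and 20 without 30 mpa B. The 14 from 60 to 90 mpa were 2, 4 and 6 without 60 mpa A, B and C, and 84 (46 higher, 38 lower) without 90 mpa A. The 7 from 90 mpa to 3 hpa were 88 (57 higher, 31 lower) without 90 mpa A, 15 without 90 mpa B, 4 without 3 hpa A and 4 without 3 hpa C. The 50 from 3 to 6 hpa were 28, 20 and 33 without 3 hpa A, B and C, 18 without 6 hpa B and 30 without 6 hpa C, and 35 (18 higher, 17 lower) without 6 hpa A. Without 6 hpa B they split into 9 higher and 9 lower. The 74 from 6 hpa to 1 dpa were 39, 39 and 43 without 6 hpa A, B and C, 42 without 1 dpa B and 32 without 1 dpa C. The 161 from 1 to 3 dpa were 85 without 1 dpa A, 89 without 3 dpa A and 80 without 3 dpa C. The 28 higher and 161 lower genes from 3 to 7 dpa were 62 and 74 without 7 dpa A and 60 and 79 without 7 dpa B. Without 7 dpa C there were 28 higher and 148 lower. With single libraries left out, lower genes from 3 to 7 dpa thus stayed the majority, while the size of their excess moved. With DESeq2 on all libraries they were not the majority (236 higher and 206 lower).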

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

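Of the comparisons described here, the fits without 90 mpa C and 7 dpa C and without the 5 shallow or low-complexity libraries (90 mpa C, 6 hpa C, 1 dpa B, 3 dpa B and 7 dpa C) were chosen only after the data were seen. No named gene changed sign under any alternative. With DESeq2 129 of 129 named gene values kept their side of the threshold, and with RLE scaling also 129. The fit of 6 libraries kept 115 and lost 9 of those it could test, the fit without a filter kept 127, lost 1 and gained 1, the fit without 90 mpa C and 7 dpa C kept 125 and lost 4, and the fit without the 5 libraries kept 124 and lost 5. Leaving out single libraries kept 739 values, lost 31 and gained 1.

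With no filter on low counts the number of changed genes was 134 at 30 mpa, 78 from 60 to 90 mpa, 51 from 90 mpa to 3 hpa, 79 from 3 to 6 hpa, 149 from 6 hpa to 1 dpa, 258 from 1 to 3 dpa and 324 from 3 to 7 dpa. Fitted on the 6 libraries of the comparison alone it was 136 at 30 mpa, 500 at 60 mpa, 233 at 90 mpa, 2415 at 3 hpa, 181 from 30 to 60 mpa, 3 from 60 to 90 mpa, 3 from 90 mpa to 3 hpa, 89 from 3 to 6 hpa, 5 from 6 hpa to 1 dpa, 3 from 1 to 3 dpa and 84 from 3 to 7 dpa. DESeq2 gave 97 from 60 to 90 mpa, 42 from 90 mpa to 3 hpa, 82 from 3 to 6 hpa, 207 from 6 hpa to 1 dpa and 442 from 3 to 7 dpa. It called 741 higher and 375 lower genes at 90 mpa against 584 and 168 in the main fit, and 736 and 138 at 3 hpa against 695 and 69. The balance of directions turned from 25 higher and 49 lower to 3 and 2 (6 hpa to 1 dpa) and from 29 and 132 to 3 and 0 (1 to 3 dpa) in the 6 libraries alone, and from 28 and 161 to 236 and 206 (3 to 7 dpa) with DESeq2. The cause was not tested in any of these.

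Without 90 mpa C and 7 dpa C there were 1205 genes at 3 hpa, 1359 at 6 hpa, 1931 at 1 dpa, 71 from 30 to 60 mpa, 23 from 60 to 90 mpa, 11 from 90 mpa to 3 hpa, 88 from 3 to 6 hpa, 315 from 6 hpa to 1 dpa and 379 from 1 to 3 dpa. Without the 5 libraries there were 211 at 30 mpa, 740 at 60 mpa, 1887 at 90 mpa, 2071 at 3 hpa, 1607 at 6 hpa, 2016 at 1 dpa, 3587 at 3 dpa, 3556 at 7 dpa, 185, 189, 95, 122, 244, 443 and 352 in the 7 steps in order of time, and 6311 over the 9 times. From 60 to 90 mpa the balance turned from 13 higher and 1 lower to 83 and 106. Comparisons that hold none of the libraries left out, such as 3 hpa, can move by the shared estimate of spread, the filter and the scaling alone. The larger counts come from fewer libraries and say nothing of which genes are shared.

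Leaving out 1 library at a time gave 63 to 81 genes at 30 mpa, 171 to 237 at 60 mpa, 386 to 1212 at 90 mpa, 528 to 602 at 3 hpa, 470 to 732 at 6 hpa, 501 to 816 at 1 dpa, 1285 to 1556 at 3 dpa and 1088 to 1789 at 7 dpa. For the steps the ranges were 17 to 40, 2 to 84, 4 to 88, 18 to 35, 32 to 62, 80 to 134 and 135 to 176 in order of time. Leaving out 1 letter in all groups gave 1454 to 2843 genes over the 9 times and 85 to 92 list tests at the preset correlation. Of the list tests passed at that value, these fits kept 245 and lost 28. The fit without 90 mpa C and 7 dpa C lost 4 and the fit without the 5 libraries 8. List tests with the estimated correlation were not run in any of these fits. Calls near 0.05, such as inflammatory genes at 1 dpa (adjusted p = 0.0499 with an estimated correlation), were thus not checked.

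No shared effect of the letters A to C was detected, which does not show that libraries of the same letter had separate origins. Deviations of libraries with the same letter from their group means correlated by 0.010 on average (-0.149 to 0.156 over 93 pairs, 5 of them over 0.1). With the letter as a block the counts were 87, 254, 753, 781, 810, 1006, 2004 and 1744 against 0 mpa, 44, 16, 5, 48, 82, 156 and 169 in the steps, 3488 over the 9 times and 91 list tests. No named gene lost its call, and no list test at the preset correlation did. List tests with the estimated correlation were not run with the block.

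The list tests depended most on the correlation assumed between genes, with 91 of 168 passed at the preset value and 37 (29 higher, 8 lower) with the estimated one. Summing the .L and .S copies gave 89 at the preset value, and the estimated correlation was not run on summed copies. In 90 mpa C 3 counts correspond to 9.05 CPM, and in 7 dpa C to 51.7 CPM.

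The joint test passed 3524 genes, but 1454 without the A libraries and 6311 without the 5 libraries. The numbers of genes with their highest fitted mean at a time share out that total, so a changed number need not mean a changed share. These numbers were unstable, and 13 of 27 moved by over 1.5 times when 1 letter was left out. Without the 5 libraries they were 942 at 0 mpa, 358 at 30 mpa, 506 at 60 mpa, 823 at 90 mpa, 726 at 3 hpa, 888 at 3 dpa and 1021 at 7 dpa. Without 90 mpa C and 7 dpa C they were 479 at 1 dpa and 634 at 7 dpa, and with no filter on low counts 647 at 7 dpa.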

Other observations

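The tests with an estimated correlation in random regroupings, of leukocyte and epidermal genes against each other, of age, of the time of day and of the leukocyte share were chosen only after the result was seen. Several tissue and pathway lists did not move as a set. Structural matrix genes had 5 higher and 2 lower of 66 members at 3 dpa, 5 and 4 adjusted over the list alone (adjusted p = 0.75 with an estimated correlation), although fn1.S of that list reached 5625 ± 381 CPM. Heat shock and unfolded protein genes had 3 higher and 1 lower of 53 at 3 hpa, 4 and 1 adjusted over the list alone (adjusted p = 0.724), and p53 and apoptosis genes 4 and 1 of 33, 6 and 1 adjusted over the list alone (adjusted p = 0.355). Endothelial genes had 2 higher of 31 at 3 hpa, 3 adjusted over the list alone (adjusted p = 0.935), with a median of -0.14 and a mean of 0.02. Of 5 tested genes of trunk and head organs 2 were higher at 3 dpa by either adjustment (adjusted p = 0.0511), tf.L among them. Ribosomal protein genes had 0 changed of 130 at 3 hpa by either adjustment and a median of -0.44, with an adjusted p of 1.51e-11 at the preset correlation and an adjusted p = 0.351 with an estimated correlation of 0.42 between members.

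The copies of a gene on the L and S subgenomes could be compared in 5751 pairs. The hypothesis that copies respond alike was set out before the result was seen. At 3 dpa both copies were called in 257 pairs, in 256 of them in the same direction. The responses differed in 52 of 871 pairs with a called copy (5.97%), which argues against alike responses in those pairs. The limits set beforehand were for pairs with a called copy, and the share of 5.97% lay between them, so the hypothesis is undecided. Of all 5751 pairs 54 differed. Pearson's r of the copies' log2 fold changes was 0.465 over all pairs and 0.64 over pairs with a called copy. Small differences were mostly not detectable, so a low share does not show that the other copies respond alike. At the other 7 times the share was 0 to 4.25%. The pairs that differed were chosen after their values were seen. Dusp5, a phosphatase of ERK, rose by 7.25 ± 0.51 for the L copy and 2.65 ± 0.42 for the S copy at 3 hpa (adjusted p of the difference = 2.83e-08). P2ry11, a nucleotide receptor, had -2.88 ± 0.47 for L and 2.39 ± 0.77 for S at 3 hpa (adjusted p = 0.00043), and irx2, a homeobox gene, -2.07 ± 0.41 and 1.52 ± 0.52 (adjusted p = 0.000987). Whether reads of 1 copy were counted for the other was not tested, and such reads could make copies look more alike.

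Muscle genes fell at 3 dpa by a median of 2.5 on the log2 scale, and 3 explanations were weighed. Scaling of the libraries was argued against, since the median was -2.50 with TMM, -2.57 with RLE, -2.53 with TMMwsp and -2.19 with total counts, the nearest to 0, where total counts moved the median of all genes to 0.37. A lower share of muscle with the other tissues alike would raise leukocyte and epidermal genes together. The mean change of leukocyte genes exceeded that of epidermal genes (0.06) by 1.03 ± 0.12 (8.38 SE over libraries), so the other tissues did not move alike. The leukocyte list had already been called higher at 3 dpa, and a rise of leukocyte genes alone makes this gap. The gap therefore cannot tell how much of the fall came from a lower share of muscle. Age of the tadpoles or time in culture cannot be told apart from amputation, because 0 libraries of unamputated tails were among those compared. A loss of muscle from the sampled tissue together with gains of other cells may account for the fall, and was not tested.

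Of 22 clock genes 4 were higher at 90 mpa and at 3 hpa, and the time of day of sampling is a candidate explanation. The list rose at 90 mpa (adjusted p = 0.032 with an estimated correlation) and did not pass at 3 hpa (adjusted p = 0.0699). The 4 members called, bhlhe40.L, bhlhe40.S, arntl.L and per1.L, were called in the same direction at 1 dpa (log2 fold changes 2.77, 2.44, 1.60 and 1.68), a whole day after amputation by the labels. Per1.L lost that call without 0 mpa A (adjusted p = 0.0776), without 1 dpa B (0.0508) or in the 6 libraries alone (0.0511), and arntl.L without 0 mpa B (0.0501). The hours of amputation and sampling are not given in the sources used here, so time of day and amputation cannot be told apart. A response of these genes to wounding stays open.

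Leukocyte genes were higher at 1 dpa, and more leukocytes in the sample is a candidate explanation. Of 16 list members with at least 5 CPM at 0 mpa 15 (93.8%) lay above 0, against 47.6% of all genes tested with that level. This share restates the rise of the list, so it does not support more cells over induction of these genes in resident cells, and the 2 cannot be told apart. The most abundant member, mpo.L, the peroxidase of neutrophils, went from 171 to 456 CPM (1.41 ± 0.34, adjusted p = 0.00579), and lsp1.L from 31.3 to 232 CPM. None of the 43 tested members belongs to another of the lists. Only cebpe.S had no read at 0 mpa, but others were near the floor there, such as cebpe.L at 0.388 CPM and cxcr1.L at 0.512 CPM.

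Splitting the 6 libraries of a comparison in all 10 ways cannot give a share under 0.05, so only the counts of the real split and the highest other are given, and in each comparison 1 of the 10 splits, the real one, gave as many genes. Against 0 mpa these were 136 and 0 at 30 mpa, 500 and 0 at 60 mpa, 233 and 0 at 90 mpa, 2415 and 0 at 3 hpa, 948 and 0 at 6 hpa, 893 and 0 at 1 dpa, 2153 and 0 at 3 dpa, and 2138 and 106 at 7 dpa. In the steps they were 181 and 2, 3 and 0, 3 and 0, 89 and 0, 5 and 0, 3 and 0, and 84 and 28 in order of time. Over 25 regroupings of the 27 libraries, the real one included, 1 gave as many genes in the joint test (3524 against at most 7). With 25 regroupings the share cannot fall below 1 in 25. The other groupings mix libraries of different times, which raises the spread within a group and lowers their counts. Chance is therefore not excluded by this comparison.

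For the list tests at the preset correlation, 1 of 25 regroupings gave as many, with 91 passed in the real grouping, but other groupings passed up to 79 and a median of 55 of 168. These groupings mix libraries of different times, so changes with time can pass lists in them as well as members that vary together within a time, and these were not separated. With an estimated correlation 1 of 25 gave as many, 37 in the real grouping and at most 0 in the others. The mixing of times limits this comparison too, so it does not exclude chance.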
